A study of Mus musculus with 2 samples.

How the data were processed

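Single cells from the tumour region of the liver were measured in C57BL/6 mice kept on a diet named CD-HFD for 15 months and recorded as 17 months old. Per the labels, an inhibitor of the fatty acid binding protein FABP5 was given from month 13, and the labels divide the series into a control library and an inhibitor library, 1 library per group. The number of mice behind each library and the treatment of the control mice were not given in the sources used here. Per the labels' protocols, the region was cut out, digested with collagenase, and live cells were enriched with an Annexin V kit, the sequenced fraction not being stated, before droplet encapsulation on a 10x Genomics 3′ platform, which tags each captured mRNA with a unique molecular identifier (UMI).

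The deposited files hold whole-number UMI counts per gene and cell barcode, without normalization, for 31053 features. Per the file headers, the count matrices were written by Cell Ranger 5.0.1. Per the submitters' processing notes, Cell Ranger, R 3.0 and Seurat 3 were used and the genome build was mm9. The feature identifiers were compared with GENCODE M21 on GRCm38, where 30934 of them (99.6%) were found, 30468 under the same symbol. The build behind the counts is therefore open, and the single genome position printed was taken from GRCm38. The deposited barcodes were already a filtered set in which no barcode of the control library had fewer than 502 UMIs and none of the inhibitor library fewer than 500.

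Barcodes with at least 300 detected genes, at least 500 UMIs and at most 25% of UMIs from mitochondrial genes were kept. Doublets were scored in each library against simulated doublets, 2 per cell, among nearest neighbours, and the highest-scoring share equal to 0.8% per 1000 barcodes was removed, which was 374 barcodes (5.47%) of the control and 717 (7.57%) of the inhibitor library. The kept cells numbered 6461 and 8753. Counts were scaled to 10000 UMIs per cell and log-transformed. Both libraries were clustered together without integration from 2000 variable genes, 30 principal components, 20 nearest neighbours and Leiden partitioning at resolution 1. This gave 27 clusters.

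Clusters were named from markers of 19 classes that were fixed before the data were examined. A marker counted when its level was at least 2-fold above that of the other clusters, and a class needed at least 3 such markers. The scoring by which markers were turned into names was changed after the first clusters had been seen, because it had left a monocyte cluster and an interferon-led macrophage cluster without a name and had called the proliferating cluster erythroid. The markers themselves were not changed. Of the clusters, 26 took a name in 15 classes, and the remaining cluster, of few UMIs, held 2.14% of control cells and 1.25% of inhibitor cells. Names are given as "-like" because they rest on these markers alone. A cluster held mostly by 1 library may reflect that library and not a cell type.

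With 1 library per group there was no test, and no p-value or standard error is given. Every difference below is between these 2 libraries, has no replicate check, and was not tested. The classes with at least 100 cells in each library, 8 of them, were compared. Shares of cells were given exact (Clopper-Pearson) 95% intervals. For genes, UMIs were summed per library and class and expressed as CPM, that is relative to all UMIs of the class, with exact Poisson 95% intervals, and ratios were given exact conditional binomial intervals. All of these intervals cover counting error only, not differences between animals, tumours or preparations. A count of 0 was set to a floor of 3 UMIs over the class, which gives a lower bound on the fold. Gene lists, 38 of them with 453 genes, were fixed before the data were examined. A list was summarised by the median log2 ratio of CPM, inhibitor over control, over members with at least 20 UMIs in the class, with a bootstrap interval over members (2000 draws) and its percentile among 10000 random lists matched on mean expression. Members at the floor entered the medians at their bound. Members were counted as higher or lower when they differed by at least 1.5-fold.

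Named genes followed a rule fixed in advance. Genes were ranked by the bound of their ratio interval nearest to 1. They needed at least 50 UMIs and detection in at least 10% of the cells of the library where they were higher. Their CPM there had to be at least 10% of that in every other named class with at least 100 cells in that library. This was meant to limit genes supplied by free RNA, although hepatocyte genes still passed in some leukocyte classes. Mitochondrial, ribosomal protein, haemoglobin, antigen receptor and unnamed genes were left out. Some genes that the rule takes are not reported here. The 10 highest and 10 lowest were taken in the 4 classes with the most cells and the 3 highest and 3 lowest in the others. The lists singled out as main results were chosen after list medians had been seen. The same rule for genes inside single clusters, and any cluster value given, was added after the data had been seen. Of the 20 named genes per large class, 7 in T cell-like and 8 in monocyte-like or macrophage-like cells also lead a cluster of the class. Their difference therefore follows, at least in part, which clusters each library fills.

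Median depth of the kept cells was 3946 UMIs in the control and 6278 in the inhibitor library. Shares of cells with a UMI of a gene were computed after thinning every cell to 1000 UMIs and are given beside the unthinned shares. The alternatives tried were a mitochondrial limit of 10% or none, at least 600 genes, no doublet removal or 2 times the removed share, Leiden resolutions of 0.5 and 2, separate clustering of the libraries, TMM scaling, means over cells, subtraction of estimated free RNA, thinned cells, and list minimums of 1 UMI in each library or 100 UMIs over both. Free RNA was estimated, outside hepatocyte-like cells, from the level of hepatocyte secreted protein genes. Its profile was the sum of all deposited barcodes of the library, a filtered set that includes the cells themselves. The subtraction therefore also removes RNA that a class expresses itself, and the estimated shares are not measured free RNA. TMM scaling shifted the log2 ratios by 0.20 in neutrophil-like and 0.13 in Kupffer-like cells and by less than 0.1 in the other compared classes, so values in the first pair of classes are read relative to those shifts.

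The counting steps were tested on simulated data made from the T cell-like sums. Counts were drawn as Poisson, the model behind the intervals, so coverage near 95% was built in. Differences between cells were not simulated. The 95% interval held the true value for 95.8% of 10782 unchanged genes, for 94.2% of 69 genes changed 1.5-fold, for 89.1% of 64 genes changed 2-fold and for 98.4% of 61 genes changed 4-fold. A planted list of 15 genes at a log2 ratio of -1 returned a median of -1.03, and an unchanged list returned -0.12. The doublet step recovered 64.1% of 323 planted doublets in the control library. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and edgeR 4.0.16 in R 4.3.3 for the TMM factors alone.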

Results

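Droplet single-cell RNA sequencing was performed on the tumour region of livers from mice on the CD-HFD diet, with 1 library from control mice and 1 from mice given a FABP5 inhibitor. FABP5 is a cytosolic carrier of fatty acids, and the design asks how cells of the tumour region differ when it is inhibited. The control library held 9493 barcodes and 53378693 UMIs, and the inhibitor library held 10649 barcodes and 68074929 UMIs. In the control library 2204 barcodes (23.2%) exceeded the mitochondrial limit, against 885 (8.31%) in the inhibitor library. Hepatocyte secreted protein genes made up 17.8% and 1.57% of the non-mitochondrial UMIs in those barcodes. Fewer than 300 genes were detected in 1506 and 917 barcodes, respectively. After all limits and doublet removal 6461 control and 8753 inhibitor cells remained, most of them leukocytes.

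Monocyte-like or macrophage-like cells made up a larger part of the inhibitor library, and most other leukocyte classes a smaller part. They were 17.7% (95% interval 16.8 to 18.6) of control cells and 46.5% (45.4 to 47.5) of inhibitor cells, a ratio of 2.63 (2.46 to 2.81). T cell-like cells were 37.0% (35.8 to 38.2) and 29.3% (28.4 to 30.3), neutrophil-like cells 12.4% (11.6 to 13.3) and 6.26% (5.76 to 6.79), and B cell-like cells 9.36% (8.66 to 10.1) and 3.96% (3.57 to 4.39). Dendritic classes were also smaller in the inhibitor library. Conventional dendritic cell 2-like cells were 4.44% and 2.74%, plasmacytoid dendritic cell-like cells 2.57% and 0.811%, conventional dendritic cell 1-like cells 1.67% and 0.857%, and mature dendritic cell-like cells 0.758% and 0.126%. Kupffer-like cells, marked by genes of the resident liver macrophages, were 2.43% (2.07 to 2.84) and 2.25% (1.95 to 2.58), and NK-like or ILC1-like cells 3.42% (2.99 to 3.89) and 2.89% (2.55 to 3.26). Hepatocyte-like cells were 3.68% (3.24 to 4.17) and 1.59% (1.34 to 1.87). The shares sum to a whole, so a larger class lowers the others. Enrichment with Annexin V, for which the labels do not say whether the bound or the unbound fraction was sequenced, and the unequal loss to the mitochondrial limit also act on these shares, and without that limit hepatocyte-like cells were 9.31% of control and 1.91% of inhibitor cells. With at least 600 genes per cell the log2 ratio of their shares was -0.51, against -1.21.

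**Figure D1:**
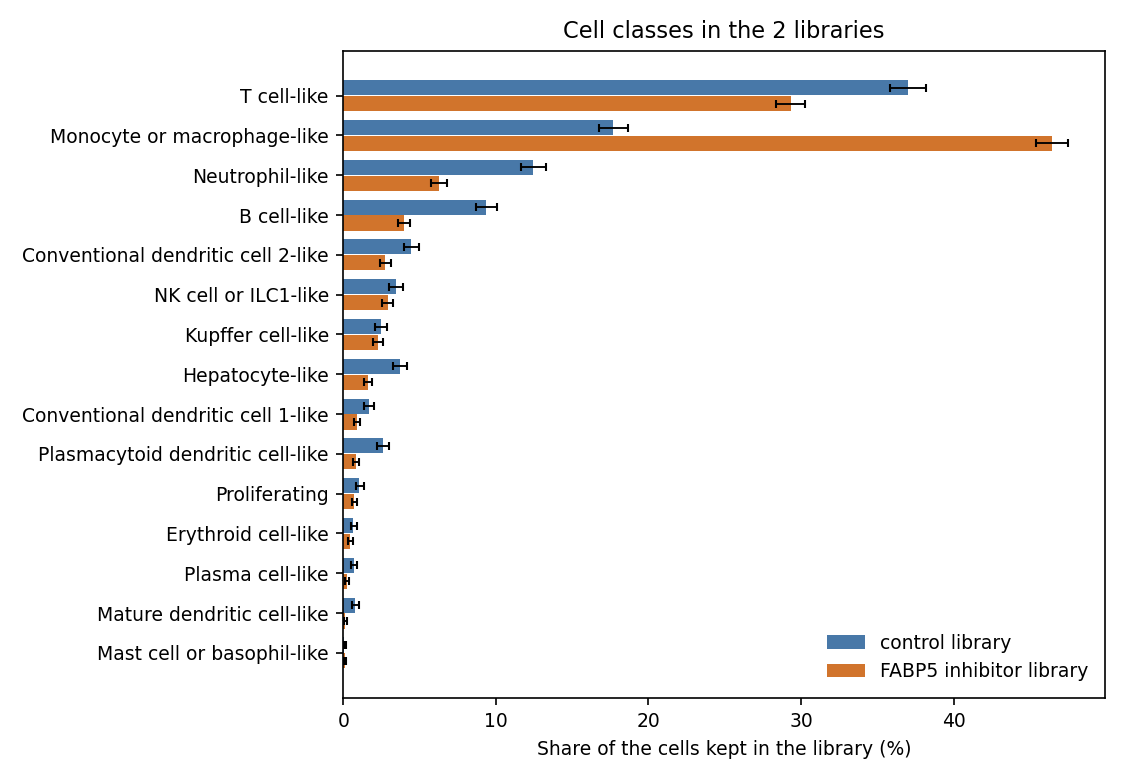
Share of kept cells in each class (percent of cells) in the control and inhibitor libraries, 1 library each; error bars are exact 95% intervals for counting error only. Monocyte-like or macrophage-like cells stand at 17.7% in the control and 46.5% in the inhibitor library.

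Different clusters held the monocyte-like or macrophage-like class in the libraries. In the inhibitor library 3368 of its 4069 cells fell in cluster 0, led by F13a1, Chil3, Fn1 and Vcan, genes of circulating classical monocytes, and 541 in cluster 8, led by Ace, Ear2 and Treml4, genes of nonclassical monocytes. In the control library 715 of its 1142 cells fell in cluster 6, led by Ms4a7, Gpnmb, Apoe and the complement C1q genes, as in tissue macrophages. The remaining control cells of the class were 113 in cluster 0, 190 in cluster 8 and 124 in cluster 19, which was led by Cxcl9, Cxcl10 and other interferon-induced genes. That last cluster held 50 inhibitor cells.

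Fabp5 mRNA, which codes for the protein the inhibitor is aimed at, was lower in the inhibitor library as a whole and in the monocyte-like or macrophage-like class, but differed much less within that class's clusters. The gene (ENSMUSG00000027533) lies on chromosome 3 from 10012548 to 10016607 on the + strand in GRCm38. An inhibitor of the protein need not change the mRNA, so its level does not check the labels, and reads of its processed pseudogene copies could be counted with it. Across all kept cells Fabp5 was at 251 CPM in the control and 91.0 CPM in the inhibitor library, with 62.3% and 59.2% of its UMIs in monocyte-like or macrophage-like cells. In that class it was at 574 CPM (559 to 589) and 91.7 CPM (88.4 to 94.999), a log2 ratio of -2.65 (-2.71 to -2.58). In cluster 6 it was at 840 and 612 CPM (log2 ratio -0.46, -0.58 to -0.34), and in cluster 8 at 120 and 88.0 CPM (-0.45, -0.73 to -0.16). In cluster 0 it was at 60.7 and 74.2 CPM, where the interval of the log2 ratio, -0.10 to 0.71, spans 0. Fabp5 is itself among the genes that lead cluster 6.

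In other classes Fabp5 was at 288 CPM (258 to 322) in the control and 355 CPM (332 to 379) in the inhibitor library for Kupffer-like cells, 273 and 256 CPM for neutrophil-like cells, and 101 and 120 CPM for conventional dendritic cell 2-like cells. Doubling the removed doublets turned the sign of the Kupffer-like and dendritic differences, to log2 ratios of -1.002 and -1.54. Mature dendritic cell-like cells held its highest level, 3625 CPM in 49 control cells and 2089 CPM in 11 inhibitor cells. T cell-like cells were at 28.1 and 17.9 CPM, and subtraction of free RNA turned the sign there, to a log2 ratio of 0.18. NK-like or ILC1-like cells were at 7.47 CPM (3.01 to 15.4) and 10.3 CPM (5.14 to 18.4). Hepatocyte-like cells were at 211 CPM and at 2.34 CPM from 3 UMIs, a log2 ratio of -6.49 (-8.78 to -4.94) that was -2.57 with no mitochondrial limit, and B cell-like cells at 9.11 CPM and at 0.949 CPM from 1 UMI, a log2 ratio of -3.26 (-8.64 to -0.62) that turned to 1.51 with no doublets removed. After thinning, 12.6% (10.7 to 14.7) of control and 6.87% (6.11 to 7.69) of inhibitor monocyte-like or macrophage-like cells had a Fabp5 UMI, leaving out 14 and 9 shallower cells. The unthinned shares, 29.7% and 30.6%, do not show that order. In B cell-like cells, which should lack the gene, the thinned shares were 1.35% and 0. The latter was 0 of 345 cells, for which the exact interval reaches 1.064% and 3 counts of the total would be 0.870%. There 12 and 2 shallower cells were left out, and the unthinned shares were 3.31% and 0.288%. Median depths were 8248 and 8119 UMIs in the former class and 3139 and 2675 UMIs in B cell-like cells.

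**Figure D2:**
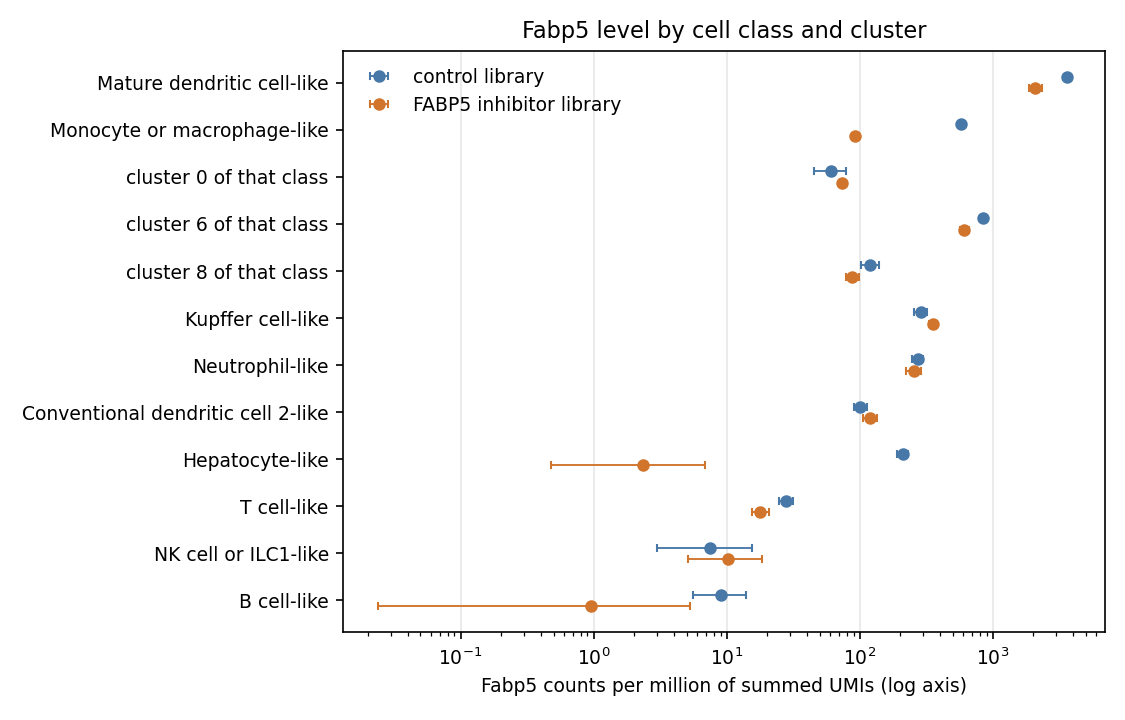
Fabp5 level (CPM, log axis) per class and in 3 clusters of the monocyte-like or macrophage-like class, in the control and inhibitor libraries, 1 library each; error bars are exact Poisson 95% intervals for counting error only. The class stands at 574 and 91.7 CPM, while its cluster 6 stands at 840 and 612 CPM.

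Monocyte-like or macrophage-like cells of the inhibitor library had higher levels of monocyte genes and much lower levels of macrophage, antigen presentation and complement genes. The C1q genes, which encode the first complement component, were among the lowest, C1qa at 1738 CPM in the control and 37.1 CPM in the inhibitor library. With separate clustering of the libraries the log2 ratios were -1.88 for C1qa, against -5.55, -1.97 for C1qb and -1.68 for C1qc. That setting gave 151 control and 0 inhibitor Kupffer-like cells. Whether the inhibitor library's Kupffer-like cells, which also carry C1q genes, entered the monocyte-like or macrophage-like class there was not tested. Pmepa1, which restrains TGF-beta signalling, was at 85.7 and 0.640 CPM, and Olfml3, Zmynd15, Tmem119, Gpr34, Cd72, Cd63, C1qb and C1qc were the other genes named as lowest, from Cd72, 26.5-fold lower by CPM, to Olfml3, 81.9-fold lower. Among the highest, the proteoglycan gene Vcan was at 27.9 and 465 CPM, the protease gene Mmp8 at 24.4 and 274 CPM, the coagulation factor gene F13a1 at 154 and 1074 CPM, and the fibronectin gene Fn1 at 192 and 1275 CPM. Noct, a circadian-regulated gene, was at 20.6 and 153 CPM, and Sgms2, Dmkn, Plcb1, Serpinb1a and Gpat3 were also higher. The monocyte marker Ly6c2 was at 420 and 937 CPM.

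By list, all 8 measured members of the MHC class II presentation list were lower in this class, with a median log2 ratio of -3.37 (-4.03 to -1.87), at percentile 0 of the random lists. H2-Aa, an antigen-presenting chain, was at 6788 and 446 CPM and Cd74, its chaperone, at 19487 and 1737 CPM. Of 14 lipid-associated macrophage genes, 11 were lower and 1 higher (median -1.91). Trem2, a lipid-sensing receptor, was at 259 and 65.5 CPM and Gpnmb at 158 and 5.73 CPM. Of 11 complement and phagocytosis genes, 9 were lower and 2 higher (median -3.82), and of 9 cholesterol efflux and LXR target genes 5 were lower (median -1.88), Abca1, a cholesterol exporter, being at 57.8 and 7.77 CPM. Of 13 interferon gamma response genes 12 were lower (median -1.59), and of 15 type I interferon response genes 13 were lower (median -1.48). With separate clustering, where the inhibitor library had no Kupffer-like cluster, the medians were smaller. They were -0.62 for complement, -0.52 for cholesterol efflux, -0.83 for interferon gamma and -0.84 for type I interferon genes. The glycolysis and hypoxia list had a median of 0.47, with 5 of 15 members higher and 1 lower. The fatty acid oxidation and PPAR target list had a median of -0.03 and the lipogenesis list one of -0.17, with intervals over members that span 0.

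These class values follow the clusters that each library filled. Within clusters 0, 6 and 8 the MHC class II median was 0.32, -0.17 and -0.50, and the lipid-associated macrophage median was -0.30, -0.68 and -0.37. The type I interferon median was -0.30, 0.06 and -0.42 in the same clusters, and the interferon gamma median -0.46, 0.165 and -0.39. Cluster 19, named from the C1q genes and Ms4a7, held 124 control and 50 inhibitor cells and is not covered by these values. Within cluster 6, which held 715 control and 110 inhibitor cells, 8 of 14 lipid-associated genes were still lower and none higher. There Trem2 was at 343 and 146 CPM, Gpnmb at 239 and 112 CPM and the tetraspanin gene Cd9 at 317 and 120 CPM. Trem2 and Gpnmb are among that cluster's leading genes. Pmepa1 there was at 118 and 7.13 CPM.

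T cell-like cells of the inhibitor library had lower interferon response genes and somewhat higher cytotoxic effector genes. All 15 type I interferon response genes were lower, with a median log2 ratio of -1.95 (-2.61 to -1.49), at percentile 0. Rsad2, an antiviral enzyme, was at 57.3 and 6.51 CPM, Isg15, a ubiquitin-like protein, at 411 and 85.4 CPM, and Cxcl10, a chemokine also made by myeloid cells, at 220 and 46.9 CPM. Ifit1, Ifit3, Ifit3b and Isg20 were also among the lowest, and UMIs of the near-identical pair Ifit3 and Ifit3b may be split between them. Of 13 interferon gamma response genes 10 were lower (median -0.81), while within clusters 2, 3, 4 and 7 the medians were 0.14, 0.39, -0.05 and -0.21. Genes of antigen-presenting cells were lower in the class too, with medians of -1.10 for MHC class II presentation (6 of 8 lower) and -0.96 for complement and phagocytosis (5 of 8 lower). Cluster 9, led by interferon genes, held 482 control and 58 inhibitor cells. Without it the type I median was -0.77, and within clusters 2, 3, 4 and 7 it was -0.30, -0.23, -0.36 and -0.56. The remaining T cell-like cells were led in the control library by cluster 3 (641 and 450 cells), with Gzmk, Pdcd1 and Tox among its leading genes. In the inhibitor library they were led by cluster 2 (340 and 912), with Cd8b1 and Gzmk, and by cluster 7 (209 and 597), with Lef1, Il7r and Tcf7. Cluster 4, with Cd4, Ikzf2 and Tnfrsf4, held 455 and 522 cells. After thinning, 19.4% of control and 6.54% of inhibitor T cell-like cells had an Isg15 UMI (unthinned 34.0% and 16.4%), leaving out 29 and 27 cells, against 0.843% and 0.870% of B cell-like cells. Median depths were 3655 and 3742 UMIs.

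The T and NK cytotoxicity list had a median of 0.37 (0.13 to 0.64) in T cell-like cells, at percentile 100, with 3 of 12 members at least 1.5-fold higher and none as much lower. Gzmb, a granule protease, was at 262 and 434 CPM, Prf1, the pore-forming protein, at 81.4 and 119 CPM, and Ifng at 110 and 162 CPM, while Gzmk was at 296 and 227 CPM. The naive and memory list had a median of 0.45 with 4 of 9 members higher, while within clusters 2, 3, 4 and 7 its medians were -0.31, -0.66, 0.42 and -0.39. Of 11 exhaustion and checkpoint genes 3 were lower (median -0.26, with an interval over members that spans 0), and within clusters 2, 3, 4 and 7 the medians were 0.35, 0.21, -0.35 and -8.43e-05. Pdcd1, which encodes the PD-1 receptor, was at 90.0 and 53.1 CPM overall and at 222 and 196 CPM within cluster 3. Outside the lists, the transcription factor genes Myc (28.1 and 66.5 CPM), Satb1 (82.6 and 169 CPM) and Klf2 (879 and 1549 CPM) were higher, as were Fcgrt, Errfi1, Dusp5, Nfkbiz, Pdlim1, Tpm4 and Mat2a. Krt83 (66.6 and 4.62 CPM), Tmem176a and Ramp1 were lower. Krt83 also leads cluster 12, whose cells expressed Il17a and Trdc.

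**Figure D3:**
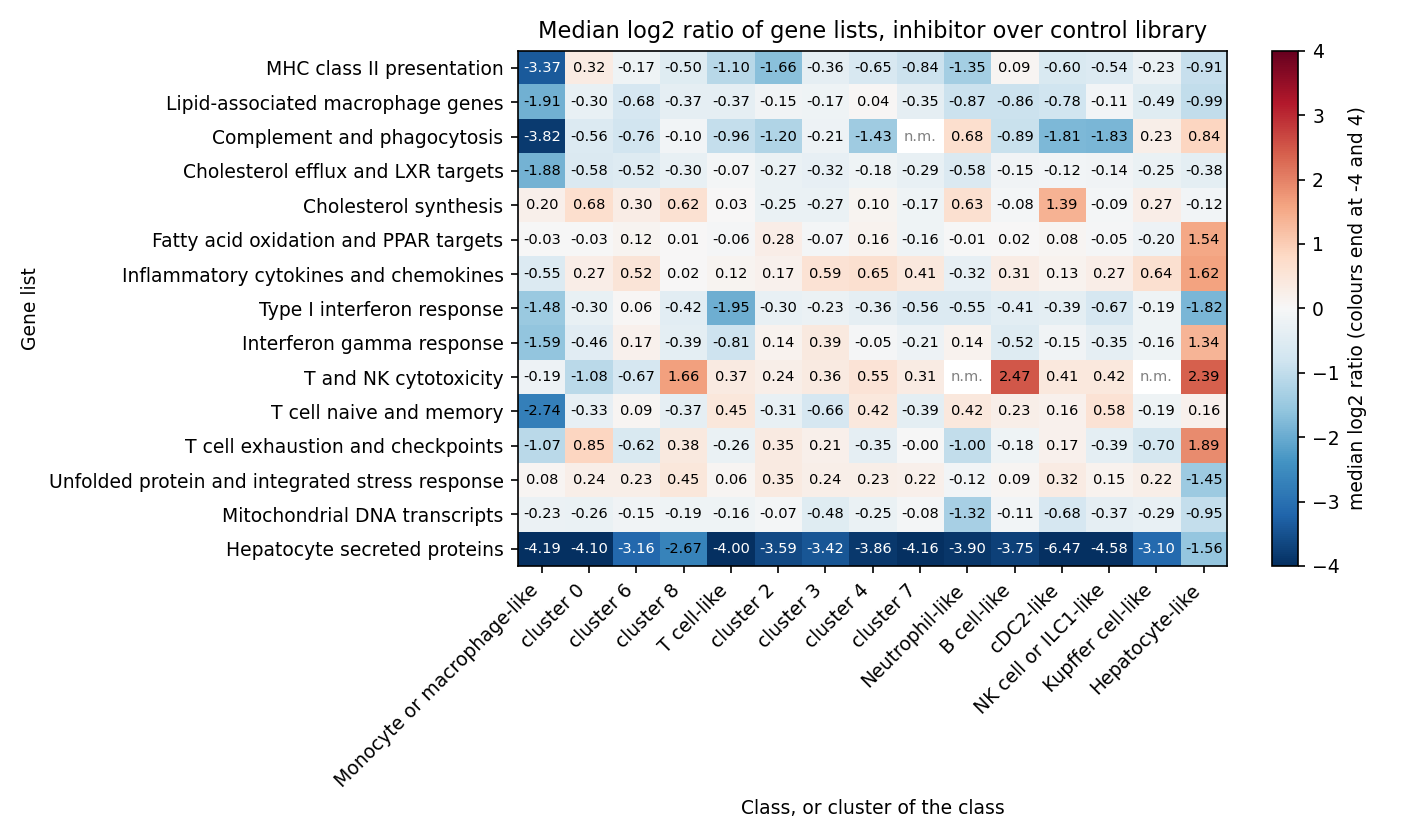
Median log2 ratio of CPM, inhibitor over control library, for selected gene lists (vertical axis) in each class and, after their class, in single clusters of it (horizontal axis), printed and as a colour scale that ends at -4 and 4; n.m. marks lists with too few measured members. In T cell-like cells the type I interferon median is -1.95 and the cytotoxicity median 0.37.

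Neutrophil-like cells of the inhibitor library had lower mitochondrial transcripts and lower Cdkn1a, Bhlhe40 and Siglecf. All 9 mitochondrial DNA transcripts were lower, with a median log2 ratio of -1.32 (-1.47 to -1.09), and the class's median mitochondrial share was 1.84% in control and 0.532% in inhibitor cells. Cdkn1a, a cell cycle inhibitor, was at 146 and 20.7 CPM, Bhlhe40, a transcription factor, at 186 and 39.3 CPM, and Scimp at 81.1 CPM and at 2.18 CPM from 2 UMIs, a log2 ratio of -5.22 (-8.28 to -3.34). Rgs10 and Mrpl52 were also lower. Siglecf, a surface lectin of the granule and maturation list, was at 99.9 and 24.0 CPM, while that list as a whole had a median of 0.14. Higher genes were Mrgpra2b (119 and 306 CPM, with near-identical family members), Ifitm6 (89.6 and 236 CPM), the adhesion receptor gene Cd44 (1085 and 1991 CPM), Slc44a1, Atp2b1, Stfa2l1, Cux1, Gk, Gda and Ripor2. The remaining genes named as lower, Apoa4 (71.3 CPM and 0, at least 21.8-fold), Alb (1355 and 77.4 CPM), Kng1 and Apoa1, are hepatocyte genes. With no doublets removed and with free RNA subtracted, the log2 ratios were -0.92 and -6.18 for the mitochondrial list, -1.15 and -5.23 for Cdkn1a, -1.66 and -3.21 for Bhlhe40, and -0.48 and -5.08 for Mrpl52. The share of UMIs estimated as free RNA in this class, from the profile of all deposited barcodes, was 21.1% and 31.2%. The hepatocyte secreted list had a median below 0 in each of the 8 compared classes (from -6.47 to -1.56), and it made up 1.49% and 0.108% of the UMIs of all barcodes.

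In B cell-like cells 24 of 31 measured lists had medians within 1.5-fold, including MHC class II presentation (median 0.09). The T and NK cytotoxicity list was higher (median 2.47 over 3 measured members). Lower were the lists of hepatocyte secreted proteins (-3.75), acute phase (-3.46), regulatory T cells (-2.06 over 3 members), complement (-0.89), lipid-associated macrophage genes (-0.86, 6 of 9 members lower) and liver tumour markers (-0.72). These are mostly genes of other cell types. The costimulatory ligand gene Cd86 was at 74.2 and 131 CPM, Peli1, a ubiquitin ligase, at 64.7 and 116 CPM, and Bank1, a B cell receptor adaptor, at 476 and 656 CPM. Fam192a, Sun2, Dhx40, Arl5c, Stap1, Cytip and Fbxw2 were also higher. Lars2, the mitochondrial leucyl-tRNA synthetase, was at 170 and 54.1 CPM, Id3 at 80.1 and 36.1 CPM and the heat shock gene Hspa1a at 226 and 127 CPM. AY036118, Crip1, Tnks2, D10Wsu102e, Sorl1, Ccnd2 and Sav1 were also lower.

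Conventional dendritic cell 2-like cells of the inhibitor library had higher cholesterol synthesis genes. Of 16 measured members 12 were higher and none lower, with a median of 1.39 (0.71 to 1.91), at percentile 100. The median was 0.74 at resolution 0.5. Fdps, an enzyme of isoprenoid synthesis, was at 20.6 and 125 CPM, Sqle, squalene epoxidase, at 5.67 and 32.5 CPM, and Idi1 at 11.7 and 46.6 CPM. Lmna, a nuclear lamin, was at 7.44 and 75.2 CPM and F13a1 at 26.2 and 188 CPM. F13a1 also leads cluster 0 and was at 1074 CPM in monocyte-like or macrophage-like cells of the inhibitor library. Its log2 ratio in the dendritic class ranged from 2.415 to 4.67 over the planned settings. Of 18 recomputed results of the class, 15 moved by over 1.5-fold in at least 1 such setting. The MHC class II median was -0.60, with 4 of 8 members lower, and Cd74 was at 25436 and 17119 CPM. The genes named as lowest, Apoa1, Kng1 and Pzp, are hepatocyte genes, and in this class the hepatocyte secreted list made up 0.272% and 0.012% of UMIs.

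Kupffer-like cells of the inhibitor library had higher monocyte-attracting chemokines and lower lipid-associated genes. Ccl7 was at 9.95 and 397 CPM, Ccl2 at 32.5 and 641 CPM and Ccl12 at 8.14 and 133 CPM. These neighbouring genes have similar sequences, so their split is uncertain. Of 15 inflammatory cytokine and chemokine genes, 8 were higher and 2 lower (median 0.64, 0.38 to 1.44). Il1b was at 316 and 643 CPM and Tnf at 24.4 and 66.4 CPM. Of 14 lipid-associated macrophage genes 6 were lower and 1 higher (median -0.49), Gpnmb being at 240 and 44.6 CPM and Trem2 at 214 and 56.7 CPM. Ddit4, a stress-induced inhibitor of mTORC1, was at 92.2 and 8.15 CPM and Arrdc3 at 121 and 19.8 CPM. Median depth differed, 3901 UMIs in control and 13333 UMIs in inhibitor cells. The share of UMIs estimated as free RNA was 15.1% and 66.3%. That estimate rests on hepatocyte secreted genes at 0.225% and 0.071% of the class's UMIs, against 1.49% and 0.108% in all barcodes. Over the planned settings the log2 ratio of Ccl12 ranged from 1.14 to 6.16 and that of Ccl2 from 4.03 to 5.98, and the inhibitor library clustered by itself gave no Kupffer-like cluster.

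NK-like or ILC1-like cells of the inhibitor library had higher cytotoxic genes, with 4 of 11 list members higher and none lower (median 0.42, at percentile 100). Gzmb was at 524 and 1003 CPM, Prf1 at 264 and 467 CPM and Ifng at 124 and 220 CPM. Pim1, a kinase, was at 210 and 524 CPM, Lmna at 9.61 and 47.7 CPM, and the NK receptor gene Klra7, which has close copies, at 54.4 and 224 CPM. Lars2 (177 and 62.7 CPM), the growth factor receptor gene Kit (95.02 and 36.5 CPM) and Fosb (120 and 50.5 CPM) were lower. Cluster 13, led by Xcl1 and Gzmc, held 156 control and 100 inhibitor cells, and cluster 16, led by Gzma and Klra8, held 65 and 153. Klra7 and Prf1 are also among the leading genes of cluster 16. Their class values therefore follow, at least in part, which clusters each library fills. Within cluster 13 the cytotoxicity median was 0.39, and the T cell gene Cd3g was at 61.3 and 216 CPM there.

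Hepatocyte-like cells of the libraries differed in zonation genes, and they lay in different clusters. Genes of hepatocytes around the central vein were higher in the inhibitor library, and periportal and tumour marker genes were higher in the control library. Of 10 pericentral genes 10 were higher, with a median log2 ratio of 6.78 (5.12 to 7.60). Glul, glutamine synthetase, was at 30.6 and 7106 CPM, Oat, ornithine aminotransferase, at 9.45 and 10772 CPM, Cyp2e1 at 6.30 and 1223 CPM and Cyp1a2 at 2.70 and 397 CPM. Of 10 periportal genes 8 were lower (median -4.12), Sds, serine dehydratase, being at 196 CPM and 0, at least 83.9-fold lower. All 12 measured liver tumour markers were lower (median -3.47), among them Spp1, osteopontin, at 11668 and 8.57 CPM and Afp, alpha-fetoprotein, at 102 and 13.2 CPM. Spink1, at 1577 CPM and 0, was at least 675-fold lower and Tspan8, at 897 CPM and 0, at least 384-fold lower. The differences of these genes were smaller in some settings, where log2 ratios reached -4.52 for Spp1 with no mitochondrial limit, -4.62 for Spink1 with no doublets removed and -4.42 for Tspan8 in thinned cells, and the tumour marker median ranged from -6.50 to -2.67. Saa3, an acute phase gene with close copies, was at 1.35 CPM from 3 UMIs and at 1711 CPM, a log2 ratio of 10.31 (8.76 to 12.59), or 7.42 with at least 600 genes per cell.

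The fatty acid oxidation and PPAR target list was higher in hepatocyte-like cells, with 15 of 18 members higher and 1 lower (median 1.54, 1.04 to 1.82). Fabp1, the liver fatty acid binding protein, was at 1995 and 27405 CPM. Unfolded protein and integrated stress response genes were lower in 11 of 14 cases (median -1.45), Hspa5, an endoplasmic reticulum chaperone, being at 680 and 181 CPM. Dissociation and immediate early genes were lower in 12 of 16 cases (median -1.78) and mitochondrial transcripts in 8 of 9 (median -0.95), and the median mitochondrial share was 7.52% in control and 0.924% in inhibitor cells. Without the mitochondrial limit the medians were 0.83 for the unfolded protein list, 0.76 for dissociation genes, 2.85 for fatty acid oxidation and 7.75 for pericentral genes, and with 2 times the doublets removed the pericentral median was 4.66. All 29 results of the class that were recomputed moved by over 1.5-fold in at least 1 setting. The class lay in different clusters in each library. Clusters 18 and 25 held 181 and 55 of its 238 control cells and 1 inhibitor cell each, and cluster 20 held 2 control and 137 of the 139 inhibitor cells. Of the control UMIs of the class, 65.1% came from cluster 25 and 34.8% from cluster 18, so the smaller number of cells weighs more in the control values. Without cluster 25, an alternative chosen after seeing the data, the medians were 5.33 for pericentral genes, -4.004 for periportal genes and -5.02 for liver tumour markers. Those of fatty acid oxidation (1.15) and unfolded protein genes (-1.48) also kept their direction. The differences of dissociation genes (-0.13) and mitochondrial transcripts (-0.06) mostly vanished. Oat and Glul lead cluster 20, and Spp1 and Tspan8 lead cluster 25, which also carried cholangiocyte markers. Cluster 18, with a median of 1582.5 UMIs, also carried the erythroid markers Hbb-bs, Hbb-bt, Hba-a1, Hba-a2 and Alas2. Its cells may therefore hold RNA of other cells, and the control values of the class are limited by both clusters.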

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

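All tests of explanations in this part were chosen after the results had been seen, and so was the size at which opposite list medians were picked out. Differences between classes were not tested.

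List medians pointed in opposite directions in hepatocyte-like and in monocyte-like or macrophage-like cells for a pair of lists. Cell cycle genes had a median log2 ratio of 0.91 over 13 members in the former and -0.94 over 14 members in the latter, a difference of 1.85, although the hepatocyte-like value turned sign in 2 alternatives. Interferon gamma response genes had medians of 1.34 over 11 members and -1.59 over 13 members, a difference of 2.94. In each of these classes different clusters hold most cells of the libraries.

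Pericentral transcripts also appeared in the barcodes left out by the limits, 2658 of the control and 1179 of the inhibitor library, which the class comparisons as reported did not use. In them Glul was at 815 CPM in the inhibitor and 9.57 CPM in the control library, Cyp2e1 at 245 and 1.58 CPM, and Oat at 335 and 5.58 CPM.

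The pericentral pattern of hepatocyte-like cells was weighed against 3 explanations. If the limits had removed pericentral cells from the control library, all barcodes together would show no excess, yet over all barcodes the list's median log2 ratio was 3.18 (1.82 to 5.51) in favour of the inhibitor library. If free RNA spread evenly over barcodes carried the list, barcodes rich in other hepatocyte transcripts would hold little more of it than the rest. In the inhibitor library the 2% of barcodes with the largest share of secreted protein genes, picked without clusters, exceeded the others by a median log2 ratio of 6.86 (6.43 to 7.42). The secreted protein genes that picked these barcodes stood at a log2 ratio of 6.97. The values therefore argue against evenly spread free RNA only, and hepatocyte RNA gathered in some barcodes was not excluded. Whether the pieces taken held another liver region or another tumour, or whether the treatment set the pattern, cannot be told apart with 1 library per group. A piece rich in tissue around central veins, or a tumour with active Wnt signalling, which drives these genes, may therefore account for it as well as the inhibitor.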

How the results depend on the processing

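Values for single clusters, those without the interferon-led cluster or the hepatocyte-like cluster with cholangiocyte markers, and shares among named immune cells came from alternatives chosen after seeing the data, the others from alternatives fixed before the data were examined. For the 14 main results the latter gave 161 values, all in the reported direction, of which 139 stayed inside the interval of the reported value and 22 moved outside it. The former gave 25 values, of which 11 stayed inside, 12 moved and 2 turned sign. For the other 180 results, 1913 of 2213 values stayed inside, 282 moved and 18 turned sign where the reported interval excludes 0. Among those that stayed or moved, 25 have the other sign, for results whose interval spans 0. Of all 194 results, 118 moved by over 1.5-fold in at least 1 setting fixed beforehand, among them all 29 of hepatocyte-like cells. Unless stated, the cause was not tested. Intervals cover counting error or the spread over list members, so deep sums such as Fabp5 leave them easily. No paired analysis was possible because each group has 1 library and no result comes from a test. Kupffer-like cells could not be compared under separate clustering, which gave 151 control and 0 inhibitor cells.

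The log2 ratio of Fabp5 in monocyte-like or macrophage-like cells was -2.58 with a mitochondrial limit of 10%, -2.77 with none, -2.58 with at least 600 genes, -2.57 with no doublets removed, -2.80 with the doublet share doubled, -2.37 at resolution 2, -2.49 with separate clustering, -2.21 as a mean over cells and -2.24 in thinned cells. In clusters 0, 6 and 8 it was 0.29, -0.46 and -0.45, the median of lipid-associated macrophage genes -0.30, -0.68 and -0.37, and that of MHC class II presentation 0.32, -0.17 and -0.50. These smaller values follow from the construction, since single clusters leave out how cells are spread over clusters. MHC class II presentation was at -4.10 with free RNA subtracted. The type I interferon median in T cell-like cells was -0.30, -0.23, -0.36 and -0.56 in clusters 2, 3, 4 and 7 and -0.77 without the interferon-led cluster. In hepatocyte-like cells the fatty acid oxidation median was 2.85 and the pericentral median 7.75 with no mitochondrial limit, and the latter was 4.66 with the doublet share doubled.

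The log2 ratio of hepatocyte-like shares was -2.29 with no mitochondrial limit, -0.51 with at least 600 genes and -0.87 with the doublet share doubled. For monocyte-like or macrophage-like shares it was 1.26 with a limit of 10%, 1.55 with none, 1.27 with the doublet share doubled and 1.29 at resolution 2. For neutrophil-like shares it was -1.21 with at least 600 genes, and for T cell-like shares -0.21 with no mitochondrial limit.

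Signs turned with no mitochondrial limit in hepatocyte-like cells for dissociation genes (0.76), MHC class I (0.46), MHC class II (0.91) and the unfolded protein response (0.83), and for complement genes in conventional dendritic cell 2-like cells (0.12). That limit removed many control barcodes rich in hepatocyte transcripts. The hepatocyte-like cell cycle median turned to -0.58 with the doublet share doubled and to -1.05 as a mean over cells. Fabp5 turned to 1.51 in B cell-like cells with no doublets removed. In conventional dendritic cell 2-like cells it turned to -0.14 with a limit of 10%, -0.26 with no doublets removed, -1.54 with the share doubled and -1.16 at resolution 0.5. In Kupffer-like cells it turned to -1.002 with the share doubled and -0.82 at resolution 2, and in T cell-like cells to 0.18 with free RNA subtracted. That subtraction also turned mitochondrial transcripts in conventional dendritic cell 2-like cells to 0.14 and pericentral genes in T cell-like cells to -0.56. The type I interferon median in NK-like or ILC1-like cells was 8.27e-03 in thinned cells. Depth limits the values that rest on few UMIs, such as Fabp5 in B cell-like cells, from 1 UMI in the inhibitor library.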

Other observations

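All tests of explanations in this part were chosen after the results had been seen, as were the clusters and the genes in this paragraph and the next. Several differences recurred in single clusters where both libraries had at least 100 cells, although the cells within a cluster can still differ in make-up. Gzmb, a cytotoxic granule protease, was higher in the inhibitor library in each of the 4 such T cell-like clusters and in an NK-like cluster. It was at 158 and 498 CPM in cluster 2, at 638 and 1477 CPM in cluster 3, at 37.3 and 120 CPM in cluster 4, at 52.5 and 71.1 CPM in cluster 7, and at 387 and 1068 CPM in cluster 13, where the T cell gene Cd3g was at 61.3 and 216 CPM and Ly6c2 at 19.5 and 176 CPM. In cluster 3, which carries exhaustion genes, Il10, an immunosuppressive cytokine, was at 17.8 and 123 CPM and the transcription factor gene Maf at 171 and 719 CPM. Cd4 was at 11.4 and 62.6 CPM and Tnfrsf4 at 32.4 and 183 CPM in this cluster, which was named in part from Cd8a and Cd8b1. Il17a, the cytokine of interleukin 17-producing T cells, was at 123 CPM in control and 5.19 CPM in inhibitor T cell-like cells. This is a value of the whole class that follows cluster 12, which Il17a leads and which held 263 control and 27 inhibitor cells. After thinning, 3.22% (2.54 to 4.01) and 0.236% (0.087 to 0.514) of T cell-like cells had an Il17a UMI (unthinned 4.52% and 0.312%). The shallower cells left out numbered 29 and 27. Of B cell-like cells, 0 of 593 and 0 of 345 had an Il17a UMI. The exact intervals of these B cell-like shares reach 0.620% and 1.064%, and 3 counts of the total would be 0.506% and 0.870%. Median depths were 3655 and 3742 UMIs in T cell-like and 3139 and 2675 UMIs in B cell-like cells.

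Myeloid clusters shared a further set. Noct was higher in the inhibitor library in clusters 0 (38.9 and 156 CPM), 6 (15.3 and 64.1 CPM) and 8 (39.8 and 148 CPM), and in the Kupffer-like cluster (28.9 and 92.4 CPM). Hspa5, an endoplasmic reticulum chaperone, was at 279 and 590 CPM, 403 and 687 CPM, and 236 and 659 CPM in clusters 0, 6 and 8. The cholesterol synthesis list had medians of 0.68, 0.30 and 0.62 in the same clusters. Ccl2 was at 165 and 385 CPM, 73.4 and 211 CPM, and 24.2 and 51.7 CPM. Lars2 and AY036118 were lower in the inhibitor library in several lymphoid and myeloid clusters. Lars2 is also among the leading genes of the unnamed cluster of few UMIs. Its median mitochondrial share was 18.7% in control and 17.4% in inhibitor cells. Whether cell or library quality had a part in the lower levels of Lars2 and AY036118 was not tested. In cluster 2 Lars2 was at 154 and 50.7 CPM and AY036118 at 448 and 252 CPM, in cluster 6 they were at 101 and 32.6 CPM and at 361 and 210 CPM.

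The larger share of monocyte-like or macrophage-like cells was weighed against 3 explanations. Blood of ordinary make-up was taken to bring more neutrophils and B cells than monocytes. Clusters 0 and 8, the larger clusters of the class in the inhibitor library, held 4.37 (4.06 to 4.70) cells per neutrophil-like or B cell-like cell there, 3909 against 895 cells. How well neutrophil-like cells survived preparation and the limits was not measured. Their median depth in the inhibitor library was 1636 UMIs, against 8119 UMIs in the monocyte-like or macrophage-like class. The ratio therefore cannot bound how many of these cells blood supplied. Neutrophil-like plus B cell-like cells per Kupffer-like cell were at 0.506 of the control ratio and per hepatocyte-like cell at 1.09, which decides nothing without a class known to be constant, and the count of clusters 0 and 8 was set against blood only after these ratios had been seen. If filters, doublet removal or clustering had made the difference, an alternative to them would bring the ratio of shares below 1.5, yet the lowest ratio over those fixed before the data were examined was 2.40. The inhibitor and other differences between mice or tumour pieces cannot be told apart with 1 library per group.

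The lower type I interferon genes of T cell-like cells were weighed against a pair of explanations. Free RNA from other cells would add the same excess to other lymphocytes, yet the excess CPM of the control library in B cell-like cells was 0.013 (-0.049 to 0.114) of that in T cell-like cells. A difference in interferon exposure of the whole sample remains open. The list's median and its interval lay below 0 in 6 of the 8 compared classes, of which NK-like or ILC1-like cells turned to 8.27e-03 after thinning. In monocyte-like or macrophage-like and in hepatocyte-like cells the libraries filled different clusters, so those class values also follow cell make-up. Within clusters 0, 6 and 8 of the former class the median was -0.30, 0.06 and -0.42, against -1.48 for the class. The summed CPM of the list were higher in the control library in T cell-like (2821 and 1063) and monocyte-like or macrophage-like cells (5062 and 2950). The same held for neutrophil-like (3622 and 3076), hepatocyte-like (1407 and 697) and NK-like or ILC1-like cells (408 and 285). The sums were close in B cell-like (636 and 613), Kupffer-like (2462 and 2459) and conventional dendritic cell 2-like cells (1935 and 2051). The requirement on these sums was added after they had been seen, whereas by medians alone the explanation would have been met. Whether the higher interferon level belongs to the whole control sample or to part of it is left open by 1 library per group.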
